A study of Homo sapiens with 2 samples.

How the data were processed

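Total RNA of a control culture and a NAA10-silenced culture, both labelled MCF-7, was hybridised to 1 array each (2 arrays in all). The array is the Affymetrix Human Gene 1.0 ST, per the labels, which reads many probes along each transcript and summarises them into 1 value per probe set. The deposited values are gene-level signals on the log2 scale. They were made by the authors with RMA, per the submitters' processing notes, a method that corrects background, equalises the distributions of the arrays and summarises the probes. The log2 unit was read from the range of the deposited values (2.98 to 14.2 on the control array and 2.85 to 14.3 on the silenced array). The program version and the set of arrays normalized together are not given in the sources used here. The sorted values of the arrays differed by at most 0.12 (median 0.012), so equalised distributions hide any difference in total RNA between the cultures. Across the 33297 probe sets the arrays correlated with Pearson r 0.997 and Spearman rho 0.996, over probe sets that are not independent replicates.

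Probe sets were named from a table of the platform's annotation. Of the 33297, 19460 had 1 gene symbol, 1754 had several and 12083 were unnamed here, which does not mean that they have no gene. Of those with 1 symbol, 19429 matched a RefSeq table of assembly GRCh38.p14, used for names and gene types only, and 0 symbols needed updating. No genome build is named for the deposited values, so no coordinates are given. NAA10 was among the genes without a named probe set and was not analysed here. Probe sets with 1 symbol gave 18417 genes. Where a gene had several probe sets (769 genes), the brightest by mean was used. A gene passed the signal floor where the higher of its 2 log2 values was at least 6, which left 13514 genes (12692 protein coding).

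For each gene the difference is the log2 value of the silenced array minus that of the control array. Because there is 1 array per group, no test was run. Genes were counted by a size of 1.5-fold. As a yardstick, each difference was divided by the robust SD (median absolute deviation times 1.48) of the 500 genes closest in brightness. For 35 gene lists the median difference over members past the floor was placed among the medians of 10000 random lists of the same size, matched on mean log2 value in 20 bins, and a list was called outside the range where its median fell beyond the central 95%. This describes these arrays and is not a test of the conditions. The lists held 858 genes, of which 777 were measured and 696 passed the floor. The background guide is the 95th percentile of the log2 signals of the 30 measured unrelated-tissue genes on each array. It was set after the data were seen, and folds are given for genes named by size only where both arrays were above it.

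The named genes followed a rule fixed before the data were examined, as were the lists and most alternatives. It takes the N-terminal acetyltransferase genes, the 12 protein-coding genes with the largest positive and the 12 with the largest negative difference among those past 1.5-fold (8 were lower), and for each list up to 4 members with the largest absolute difference. Genes named for their level as cell-type markers were picked from the marker lists after their values were seen. The differences of PDGFRB and VIM were also named outside the rule, after the values were seen. The alternatives were centring on the median of all probe sets, removing a loess trend on brightness, centring on ribosomal protein genes, adding an offset of 32 to linear signals, floors of 5 and 7 or none, a size of 2-fold, the mean over the probe sets of a gene, probe sets with several symbols counted under the first, all measured list members, and random lists not matched on brightness. Lists without their 4 largest members, and 5 second lists of other genes, were added after the data were seen. Probe sets with no symbol or several symbols were left out of gene counts.

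The procedure was tested on simulated data for the silenced against the control array, on 18417 genes. It recovered 99 of 100 genes given a 2-fold difference and 82 of 100 given 1.6-fold, with 0 of 13256 unchanged genes past 1.5-fold. The changed genes were drawn only from those with a higher log2 value of at least 7. The noise was normal with 1 SD for all genes, although real spread was wider in dim genes (robust SD 0.15 at mean signals of 6 to 7, 0.073 from 11). The count of 0 follows from that setting and does not cover dim genes. Of 200 unchanged lists of 30 genes 13 fell outside the range (6.5%), and 46 of 50 lists shifted by 0.1 were found (92.0%). The simulation holds only the noise put into it and not the variation between cultures. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.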

Results

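Gene expression was measured in a pair of cultures labelled MCF-7, an established human breast cancer cell line that is known for its oestrogen receptor and its epithelial character. Both had been infected for 120 h with a lentivirus, which carried a control construct in the control culture and a short hairpin RNA against NAA10 in the other. NAA10 is the catalytic subunit of NatA, the enzyme complex that acetylates the N-terminus of many newly made proteins. Total RNA of each culture was read on 1 Affymetrix Human Gene 1.0 ST array, and the arrays are called the control array and the silenced array after their labels. The stated aim was to learn how NAA10 holds back metastasis. Signals on the log2 scale had a median of 6.87 on the control array and 6.85 on the silenced array, over 33297 probe sets. With 1 array per group no difference has a replicate check, no test or error can be given, and the number of arrays limits the precision of every value.

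The silenced gene itself could not be used to check the labels, because its probe set is not named in the annotation used here and its level was not analysed here. Of the 14 N-terminal acetyltransferase genes, 9 were measured and 0 of them differed by 1.5-fold between the arrays. NAA15, the subunit that anchors NAA10 to the ribosome, was higher on the silenced array by 0.25 on the log2 scale (10.58 on the control array, 10.83 on the silenced array, 1.19-fold). NAA16, a paralog of NAA15, differed by -0.11, and NAA50, the acetyltransferase bound to NatA, by -0.02. Among the other complexes, NAA60 differed by 0.12, NAA25 by -0.07, NAA30 by -0.06, NAA35 by 0.03, NAA20 by 0.03 and NAA38 by -0.02. The median of the 9 genes was -0.017, inside the range of 95% of random lists of similar brightness (-0.081 to 0.078).

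On both arrays several genes that mark oestrogen receptor positive epithelium read low. The shares of their lists above a guide to background, given below, were close to or above that of all genes. ESR1, the oestrogen receptor, read 5.54 on the control array and 5.57 on the silenced array. Its target PGR, the progesterone receptor, read 4.98 and 4.93, and GREB1, another target, 5.49 and 5.45. E-cadherin (CDH1) read 6.36 and 6.34, EPCAM 5.89 and 5.99, and the luminal keratin KRT19 6.70 and 6.55. For comparison, the 95th percentile of 30 genes of unrelated tissues was 7.27 on the control array and 7.33 on the silenced array, with 2 of 30 above it on each. This guide to background is rough because probe sets differ in affinity. Several mesenchymal genes were bright, with the intermediate filament vimentin (VIM) at 11.65 and 11.58, fibronectin (FN1) at 11.44 and 11.82, N-cadherin (CDH2) at 10.40 and 10.56, and the transcription factor SNAI2 at 10.52 on both. Of 28 measured mesenchymal genes, 20 lay above the guide on the control array (71.4%), against 8 of 15 luminal genes (53.3%), 16 of 25 epithelial junction genes (64.0%), 16 of 27 oestrogen-induced genes (59.3%) and 53.7% of all 18417 genes. Simple-epithelium keratins were bright as well, KRT8 at 13.10 and 13.04 and KRT18 at 12.45 on both. On the control array the epithelial junction genes CLDN7 (10.38) and JUP (11.42) were bright too, as was XBP1 (10.43) of the luminal list. Every direction given here therefore compares cells labelled MCF-7 in which ESR1, PGR, GREB1, CDH1, EPCAM and KRT19 read below the background guide.

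**Figure D1:**
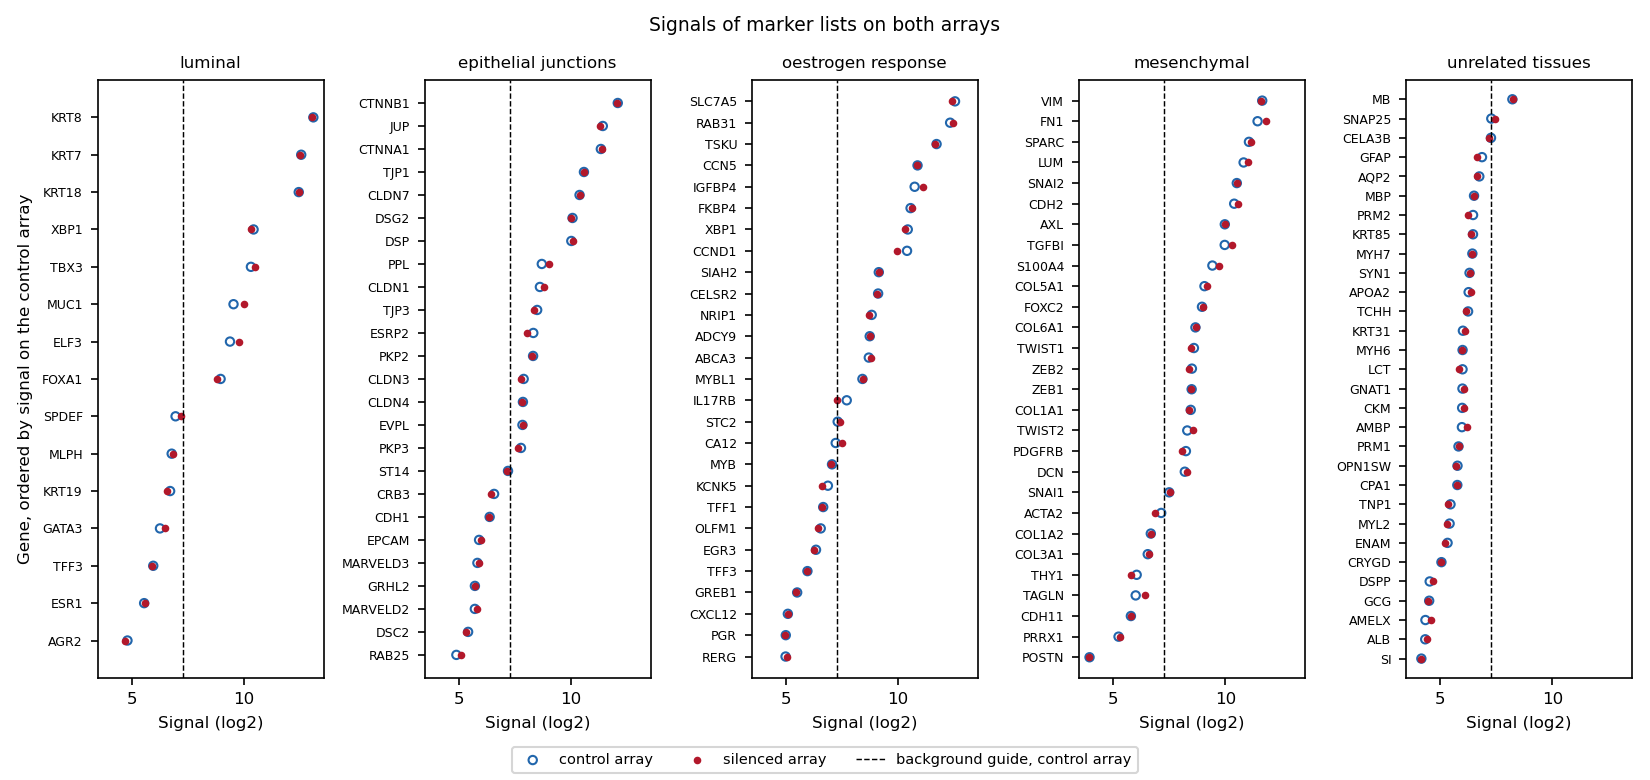
Log2 signal of each measured member of 5 marker lists on the control array (open circles) and the silenced array (filled points), with the 95th percentile of the unrelated-tissue genes on the control array as a dashed line. ESR1 (5.54), CDH1 (6.36) and EPCAM (5.89) sit left of the line at 7.27, and VIM (11.65), FN1 (11.44) and SPARC (11.06) sit far to its right.

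The question of which genes differ between the silenced and the control culture was answered by size. Among named genes above the background guide on both arrays, TNFSF10, the death ligand TRAIL, had the largest difference (7.53 on the control array, 8.45 on the silenced array, 1.89-fold higher). The neutral amino acid transporter SLC6A15 was 1.73-fold higher, the complement inhibitor C4BPA 1.67-fold, the protease inhibitor SERPINE2 1.65-fold and the lubricin gene PRG4 1.61-fold. FOSL1, which encodes the AP-1 subunit FRA-1, was higher by 0.68 on the log2 scale. The zinc finger gene ZNF814 was 1.61-fold lower. The tubulin gene TUBB2A was 1.58-fold lower by the brightest of its 3 probe sets. Another probe set of it differed by 0.15 in the opposite direction, and the mean over the 3 differed by -0.12.

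Another 4 of the 20 genes named by size were above the guide on 1 array only, so their log2 differences are approximate. They were the co-chaperone gene DNAJC12 (0.75), the tetraspanin gene TSPAN1 (0.69), the docking protein gene DOK1 (-0.59) and the histone gene H2BC3 (-0.63), which is uncertain also because its family holds near-identical copies. The remaining 8 were above the guide on neither array, and no fold is given for them. Of these, ABCA1, the cholesterol efflux transporter, read 6.24 on the control array and 7.12 on the silenced array (difference 0.88), and the phospholipase C gene PLCD4 differed by 0.84, the small GTPase gene RAB42 by 0.72 and the G protein subunit gene GNA15 by 0.69. GSPT2, a translation termination factor, read 6.69 and 5.78 (difference -0.91), and the beta-defensin gene DEFB1 differed by -0.88, the cytokine gene IL6 by -0.71 and the fatty acid hydroxylase gene CYP4V2 by -0.70.

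Of 13514 genes with a log2 signal of at least 6 on either array, 15 were at least 1.5-fold higher and 9 at least 1.5-fold lower on the silenced array, together 0.178%, and 0 reached 2-fold. Protein-coding genes made up 13 of the 15 and 8 of the 9, and 8 of the 15 and 4 of the 9 were above the background guide on at least 1 array. With the arrays aligned on ribosomal protein genes the counts were 23 higher and 8 lower. The robust SD of the differences over the 13514 genes was 0.12, and 95% of them differed by less than 1.22-fold. The differences of the 20 named genes were 4.17 to 6.80 times the robust SD of genes of similar brightness, which describes the spread between genes and not an error of any gene. With 32 added to the linear signals, which damps dim genes, 9 were higher and 3 lower. Across the 489 genes for which differences could be compared between separate probe sets, 346 had the same sign (Pearson r 0.480, Spearman rho 0.498 across genes, which are not independent replicates).

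**Figure D2:**
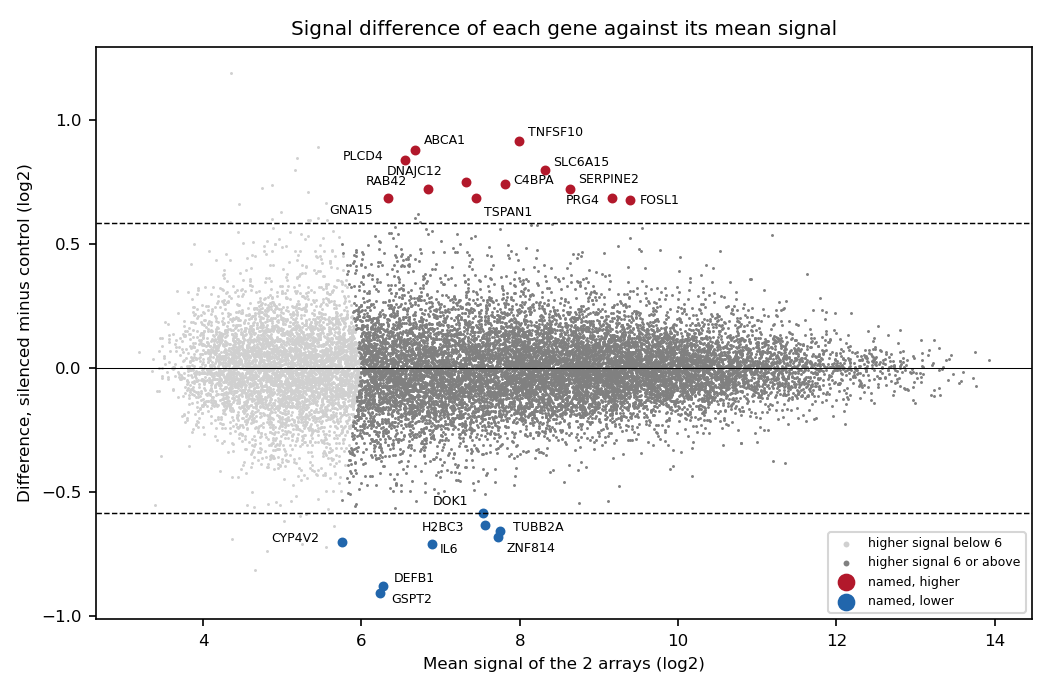
Log2 difference of each gene (silenced minus control) against its mean log2 signal on the 2 arrays, with dashed lines at 1.5-fold. The named genes, from TNFSF10 at 0.92 to GSPT2 at -0.91, lie outside a cloud that is narrower among bright genes, and GSPT2 and 7 others of them read below the background guide on both arrays.

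Mitosis and DNA replication genes were lower on the silenced array as groups, each by a small amount. In the G2/M and mitosis list 31 of 35 genes lay below 0, among them CDC20, an activator of the anaphase-promoting complex (-0.37), its ubiquitin-conjugating enzyme UBE2C (-0.30), the mitotic kinesin KIF20A (-0.25) and the mitotic kinase PLK1 (-0.21). The median was -0.074, and 1 of 10000 random lists matched on brightness was as low. In the G1/S and replication list 26 of 35 lay below 0, with a median of -0.065 (12 of 10000 random lists as low). There the ribonucleotide reductase subunit RRM2 differed by -0.32, E2F8 by -0.26 and GINS3 by -0.23, while the helicase subunit MCM6 was higher by 0.32. Replication-dependent histone genes had a median of -0.059 over 25 genes, below the random range of -0.055 to 0.047, with 16 below 0. H2BC3 differed by -0.63, H2AC4 by -0.38 and H3C1 by -0.37, against 0.48 for H2AC11. These copies are near-identical, so single members are uncertain, and without these 4 genes the median of -0.054 was inside its random range. Apart from H2BC3, 0 genes of these lists reached 1.5-fold.

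Matrix proteases and their inhibitors were higher on the silenced array, the direction of 24 of the 30 genes above the signal floor. Their median of 0.11 lay above all 10000 random lists (random range -0.055 to 0.038). SERPINE2, which inhibits thrombin and plasminogen activators, was higher by 0.72, the metalloproteinase inhibitor TIMP4 by 0.49 and the gelatinase MMP2 by 0.37, whereas the secreted protease ADAMTS1 differed by -0.40. SERPINE2 was the 1 member past 1.5-fold. The mesenchymal genes FN1 and LUM were higher on the same array, by 0.38 and 0.20. In the mesenchymal list, however, 9 of 25 genes lay below 0, among them PDGFRB (-0.19) and VIM (-0.08). Genes of the TGF-beta pathway had 12 of 17 members above 0 and a median of 0.094 (18 of 10000 random lists as high). The matrix protein gene TGFBI was higher by 0.34 and the transcription factor BHLHE40 by 0.31, while the widely used TGF-beta targets THBS1 and CCN2 differed by -0.20 and -0.18. Integrin and focal adhesion genes had a median of 0.044 over 28 genes, just above the random range of -0.045 to 0.040, with 16 above 0. TNS1 was higher by 0.37, the integrin subunits ITGB1 by 0.26, ITGB8 by 0.24 and ITGA5 by 0.24. Without these 4 genes the median was -0.0083, so the direction rested on them, and the list was outside the range in 7 of 12 settings.

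Hypoxia-induced genes were mostly higher, 20 of 28, with a median of 0.057 (33 of 10000 random lists as high). NDRG1 was higher by 0.42, the ER oxidase ERO1A by 0.30 and the hormone gene STC1 by 0.28, whereas EGLN3, an oxygen sensor, differed by -0.30. Without these 4 genes the median was 0.041, inside its random range. Autophagy, lysosome and mTOR pathway genes had 21 of 29 members above 0 and a median of 0.060 (33 of 10000 as high), among them WIPI1 (0.25) and the autophagy kinase ULK1 (0.23). In that list the translation repressor EIF4EBP1 differed by -0.26 and the mTOR inhibitor TSC2 by -0.23. Notch pathway genes had a median of -0.093 over 14 genes, at the lower edge of the random range (250 of 10000 as low), with NRARP at -0.39, NOTCH1 at -0.30, DLL4 at -0.18 and the ligand JAG1 at 0.19. That list was outside the range in 4 of 12 settings. Among the list members named for their differences, EGLN3, DLL4, SOCS2, TAGLN, ELMO1, KCNK5, JAK3, OAS2, MX1, IL11, CXCL8, DUSP6, BIK and LEF1 read below the background guide on both arrays, so their values are uncertain. In total 9 of the 35 lists lay outside the range of their random lists, 5 above and 4 below. By chance 1.75 would be outside if the genes of a list varied independently of each other, as in the random lists. Genes of a list can vary together, so 9 against 1.75 does not measure an effect of silencing.

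**Figure D3:**
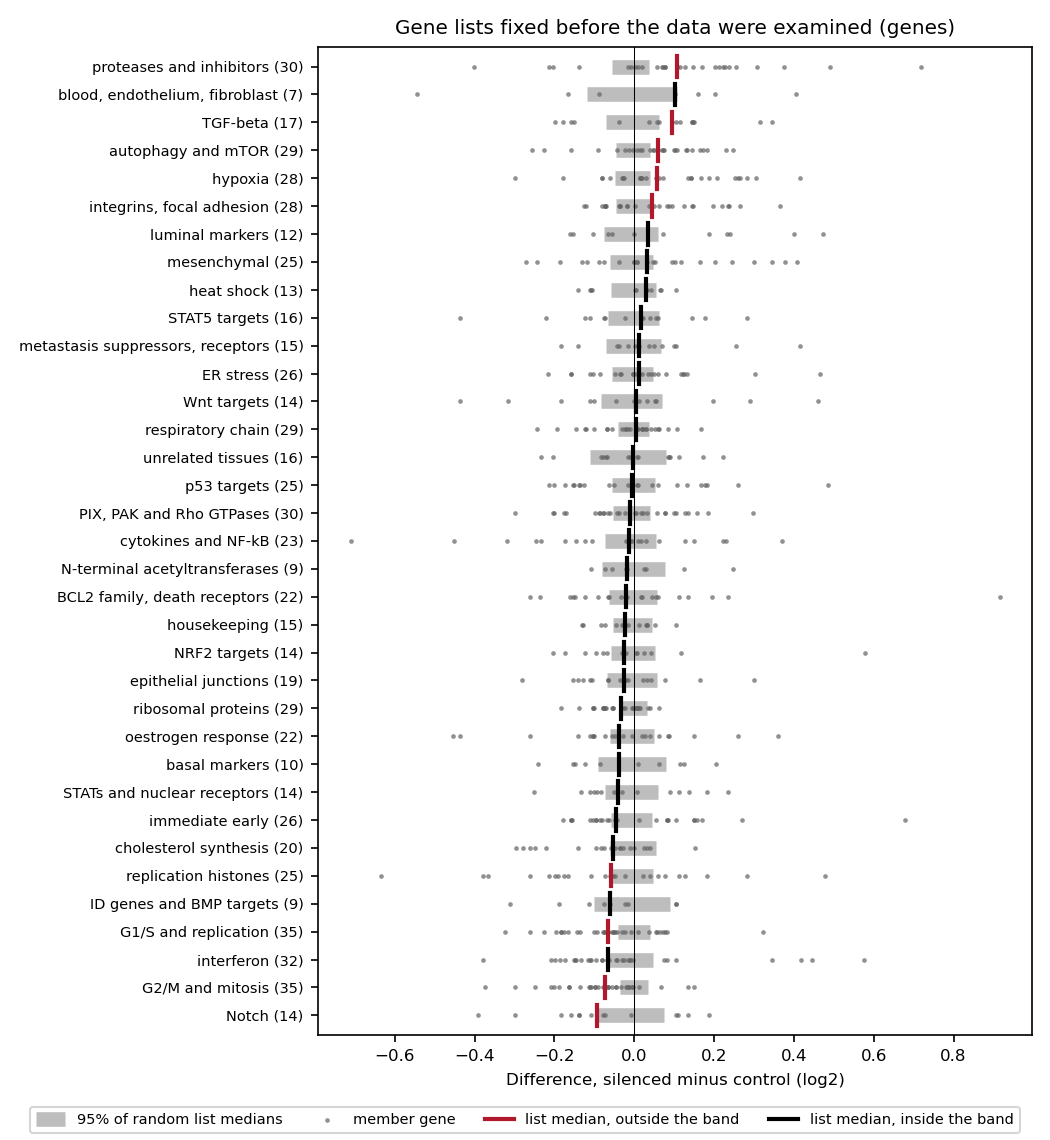
Log2 differences (silenced minus control) of the members of 35 gene lists, with the number of genes in parentheses, each list's median as a vertical bar, and a grey band holding 95% of the medians of 10000 random lists matched on brightness. Medians run from -0.093 (Notch) to 0.11 (proteases and inhibitors), and 9 lie outside their band.

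The PIX and Rho, STAT5, ID, mesenchymal, epithelial junction and metastasis suppressor lists were within the range of random lists, unlike the protease, TGF-beta and focal adhesion lists. The guanine nucleotide exchange factors PIX with their partners GIT and PAK and the Rho-family GTPases were evenly divided, 15 above and 15 below 0 (median -0.0099), with CDC42 at -0.30, GIT1 at 0.30, RHOB at -0.20 and ELMO1 at -0.20. Genes commonly described as STAT5 targets had a median of 0.017 over 16 genes. Among them the cyclin gene CCND1 differed by -0.44, the repressor BCL6 by 0.28 and the cytokine feedback genes CISH and SOCS2 by -0.22 and 0.18. ID genes and BMP targets had a median of -0.061 over 9 genes, with ID2, an inhibitor of basic helix-loop-helix factors, at -0.31, SMAD6 at -0.19 and HEY1 at 0.10. Mesenchymal genes had a median of 0.033 over 25 genes, with TAGLN at 0.41, FN1 at 0.38 and S100A4 at 0.30. A second mesenchymal list, written after the first was seen, lay above its range, with a median of 0.058 over 14 genes (range -0.059 to 0.049). Epithelial junction genes had a median of -0.026 over 19 genes, with the desmosomal gene PPL at 0.30 and the splicing regulator ESRP2 at -0.28. Metastasis suppressors and growth factor receptors had a median of 0.013 over 15 genes, with NDRG1 at 0.42 and RECK, a membrane inhibitor of metalloproteinases, at 0.26, against -0.18 for the receptor gene FGFR3 and -0.14 for the metastasis suppressor BRMS1.

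Oestrogen-induced genes had a median of -0.038 over 22 genes, with 13 below 0, again within the random range, and medians of 0.0074 with a floor of 7 and 0.0013 with ribosomal protein centring. IL17RB differed by -0.45, CCND1 by -0.44, the growth factor binding protein gene IGFBP4 by 0.36 and the potassium channel gene KCNK5 by -0.26. Luminal markers had a median of 0.035 over 12 genes, with the mucin gene MUC1 at 0.47 and the epithelial transcription factor ELF3 at 0.40, and basal markers one of -0.039 over 10 genes. Without their 4 largest members these medians were -0.061 (luminal) and 0.035 (basal), so neither had a settled sign. STATs, nuclear receptors and their coregulators had a median of -0.041 over 14 genes, with JAK3 at -0.25 and NCOA2 at 0.24. Markers of blood, endothelium and fibroblasts passed the signal floor in 7 cases, with a median of 0.10 inside a wide random range (-0.12 to 0.11). That median was -0.032 with an offset of 32 and -0.052 with a floor of 5, and with several symbols counted it was 0.13, above its range (upper end 0.097). The endothelial cadherin gene CDH5 differed by -0.54 and the matrix gene LUM, bright on both arrays, by 0.20, while the dim genes HBB and CD14 differed by 0.41 and -0.17.

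Interferon-stimulated genes were split. While 25 of 32 lay below 0 and the median was -0.066, close to the lower end of the random range at -0.067, the antiviral genes IFI44L, OAS1 and OAS2 were higher by 0.57, 0.45 and 0.42, and MX1 differed by -0.38. The list was below its range in 6 of 12 settings, for example with a loess trend on brightness removed (median -0.057, lower end -0.056) and with an offset of 32 (-0.065, lower end -0.052). Cytokine and NF-kB genes had a median of -0.012 over 23 genes, with IL6 at -0.71, RELB at -0.45, IL11 at 0.37 and CXCL8 at -0.32. Immediate early genes had a median of -0.045 and a mean of 0.021, opposite in sign, over 26 genes, with FOSL1 at 0.68 and the phosphatase gene DUSP6 at 0.27. BCL2 family and death receptor genes likewise had a median of -0.021 and a mean of 0.018 over 22 genes, with TNFSF10 at 0.92, its receptor TNFRSF10A at -0.24 and the pro-apoptotic genes BIK and BMF at -0.26 and 0.23.

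Stress and metabolic lists were also within their random ranges. The p53 targets had a median of -0.0046 over 25 genes, with the growth arrest gene GADD45A at 0.49, XPC at 0.26, TP53INP1 at -0.21 and PPM1D at -0.20. Unfolded protein response genes had a median of 0.013 over 26 genes, with the chaperone gene DNAJB9 at 0.47 and the transcription factor DDIT3 at 0.30, against SDF2L1 at -0.22 and PPP1R15A at -0.16. Heat shock genes had a median of 0.030 over 13 genes, although the chaperone genes HSPB1, DNAJB1 and HSPA8 differed by -0.14, -0.11 and -0.11. Wnt targets had a median of 0.0047 over 14 genes, with the Wnt deacylase NOTUM at 0.46, CCND1 at -0.44, SP5 at -0.32 and LEF1 at 0.29. In the cholesterol synthesis list 16 of 20 genes lay below 0, with a median of -0.053 (random range -0.060 to 0.054). They included MVK (-0.30), INSIG1 (-0.28), CYP51A1 (-0.26) and STARD4 (-0.25). The less bright probe set of CYP51A1 differed by -0.042. NRF2 targets had a median of -0.026 over 14 genes. AKR1C1 among them was higher by 0.58 by its brighter probe set and by 0.17 by the other, and it has a close paralog in AKR1C2. FTL, GCLM and NQO1 differed by -0.20, -0.17 and -0.12. Medians were -0.032 for 29 ribosomal protein genes, 0.0045 for 29 respiratory chain genes, -0.023 for 15 housekeeping genes and -0.0019 for 16 unrelated-tissue genes above the floor. Of the 26 lists inside their random range, 15 had a median that turned its sign in at least 1 other setting, the ribosomal protein genes among them (0.0075 with the arrays aligned on these genes).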

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

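The grouping of the probe sets outside the gene counts by their numbering was chosen after the values were seen. Among 2828 unnamed probe sets past the signal floor and numbered after the first named one, 19 were at least 1.5-fold brighter and 20 at least 1.5-fold dimmer on the silenced array (1.38%, against 0.203% of probe sets with 1 symbol). Of these, 5 were at least 2-fold brighter and 3 at least 2-fold dimmer. Probe set 7910636 read 5.31 on the control array and 6.85 on the silenced array, 7924307 read 4.87 and 6.39, and 7937104 read 6.27 and 4.86. Probe set 7983661 differed by -1.17. All 4 lay below the background guide of 7.27 on the control array and 7.33 on the silenced array, so no fold is given. Their genes were not looked up.

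Unnamed probe sets numbered before the first named one came to 4203, of which 3045 passed the floor. Of these 89 were at least 1.5-fold brighter and 134 at least 1.5-fold dimmer (7.32%), with a robust SD of differences of 0.23 against 0.13 for probe sets with 1 symbol. What they measure is not stated in the sources used here.

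Of 1296 probe sets with several symbols past the floor, 4 were at least 1.5-fold brighter and 5 at least 1.5-fold dimmer. Some of these repeat each other with identical values, namely those of ATP6V1G2, of ZNF75D and of a POM121L group, so fewer measurements are distinct. Probe sets with several symbols were left out of the gene counts because their signal cannot be given to a single gene.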

How the results depend on the processing

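The lists without their 4 largest members were chosen after the data were seen; the other settings were planned. The counts of 15 genes higher and 9 lower stayed within 1.5 times with median centring (16 and 8), a loess trend removed (19 and 8), a floor of 7 (12 and 6), the mean of probe sets (15 and 8) and several symbols counted (16 and 11). Ribosomal protein centring shifts all values, by an amount comparable to the list medians (median of all probe sets -0.0066 as deposited, 0.033 centred). With it 23 genes were higher, and medians were -0.034 for G2/M, -0.025 for G1/S, -0.020 for histones, -0.053 for Notch, 0.083 for focal adhesion, 0.097 for hypoxia and 0.099 for autophagy. The random ranges shifted too, and these lists stayed outside theirs. An offset of 32 gave 9 higher and 3 lower, since it shrinks dim differences. No filter gave 31 and 18, and a floor of 5 gave 28 and 17, because more dim genes entered. At 2-fold, 0 were higher and 0 lower. Of 120 values for the named genes 111 moved by less than the spread of similar genes and 9 moved by more. The protease, TGF-beta, autophagy, G2/M and G1/S lists were outside their random range in 12 of 12 settings, hypoxia in 11, histones in 10, focal adhesion in 7 and Notch in 4. The interferon list, inside its range as reported, was outside in 6. Focal adhesion turned to -0.0083 without its 4 largest members. No leave-one-out value exists with 1 array per group, and no paired analysis was possible because the groups share fewer than 2 replicate numbers. Signals near background limit the dim genes: 4903 genes lay under the floor.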

Other observations

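The gene families, the second gene lists, CDKN2A and MTAP were chosen after the data were seen; the tests on the second lists were written before their own values were, except that setting their shares against the share of all genes was added after, as was reading a trend with brightness from them. Serpins, a family of protease inhibitors, had 9 of 13 members above 0 on the silenced array and a median of 0.12 (random range -0.10 to 0.083), with SERPINB5 higher by 0.56. With dim genes included the median was 0.042 over 33 genes, inside the range of -0.063 to 0.053. Tetraspanins, the family of TSPAN1, had a median of 0.055 over 17 genes, inside the range of -0.075 to 0.062, and 0.091 over 22 genes with dim members included, above the range of -0.068 to 0.057. SNORD116 small nucleolar RNAs had a median of 0.084 over 14 probe sets (range -0.079 to 0.066), and these near-identical copies are uncertain one by one. Zinc finger genes named ZNF (median -0.0020 over 364 genes) and mitochondrial ribosome genes (-0.0054 over 74) stayed within their ranges, as did mitochondrial tRNA synthetases (-0.049 over 16), keratins (-0.015 over 34) and aldo-keto reductases (0.0026 over 7). Olfactory receptor genes had a median of 0.00088 over 361 genes with no floor. A second mesenchymal list had 11 of 14 genes above 0 and a median of 0.058, above its range of -0.059 to 0.049, with EMP3 at 0.15 and IGFBP7 at 0.13. A second list of 28 interferon-related genes had a median of -0.015, within its range, with PSMB8 at -0.25. CDKN2A, which encodes the cell cycle inhibitor p16, was higher by 0.53 (10.92 on the control array and 11.45 on the silenced array).

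On both arrays labelled MCF-7, ESR1, PGR, CDH1 and EPCAM read below the background guide and VIM, FN1, CDH2 and SNAI2 far above it. On the control array 64.0% of epithelial junction and 59.3% of oestrogen-induced genes lay above the guide, against 53.7% of all genes. How bright these lists should be in MCF-7 cells is not known here, without other MCF-7 arrays. An effect of NAA10 silencing is argued against, since the control array shows the same levels of these markers. A second luminal list differed between the arrays by a median of 0.011. Cells unlike MCF-7 and MCF-7 cells with an admixture of other cells cannot be told apart. The rule written beforehand asked whether at least 50% of a second list lay above the guide on the control array. A second mesenchymal list of 15 genes met it (80.0%) and a second luminal list of 29 genes did not (44.8%). The exact 95% intervals of 51.9 to 95.7 and 26.4 to 64.3 treat genes as independent and hold no variation between cultures. By the rule alone the result went with cells unlike MCF-7 and not with an admixture. The luminal interval, however, includes the 50% of the rule. Both intervals include the 53.7% of all genes, a comparison added after the data were seen. An admixture could brighten mesenchymal genes as well, so these shares do not decide. CDKN2A and MTAP, which are known to be deleted in MCF-7, read 10.92 and 8.58 on the control array. Both values were above the guide of 7.27 and above all 30 unrelated-tissue genes (at most 8.21). On the silenced array these genes read 11.45 and 8.71. For these genes, chosen after the data were seen, such signals argue against cultures of MCF-7 cells alone. Either cells unlike MCF-7 or an admixture would give them.

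Mitosis and DNA replication genes were lower on the silenced array. A second list of 54 mitosis genes sharing none with the first had a median of -0.063 (range -0.035 to 0.030, 37 genes below 0, CDCA3 at -0.41 and CCNF at -0.29), as a lower level of proliferation genes would give. Since the random lists were matched on brightness, a trend with brightness alone would have left it inside that range. The second list was read on the same arrays as the first, so it is not an independent check. The state of the single culture, such as its density at harvest, stays open with 1 array per group and cannot be told apart from an effect of silencing NAA10.

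Protease and inhibitor genes were higher on the silenced array. A second list of 59 matrix and protease genes, which shares members with the serpins above, had a median of 0.069 (range -0.042 to 0.031). Of these genes 43 lay above 0, with SPINT1 at 0.49, so a higher level of such genes extends past the first list. It was read on the same arrays as the first list, so it is not an independent check. A trend with brightness alone would have left the second list inside the range of random lists matched on brightness. The second mesenchymal list (0.058), FN1 (0.38) and LUM (0.20) were higher on the same array. The first mesenchymal list was inside its random range (median 0.033), with 9 of 25 genes below 0, among them PDGFRB (-0.19) and VIM (-0.08). Whether the share of other cells differed between the cultures was not tested. The state of the single culture (1 array per group) cannot be told apart from an effect of silencing.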
